A study of Mus musculus with 2 samples.

How the data were processed

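Total RNA of mouse peritoneal macrophages, extracted with Trizol and column purification from cells in DMEM with serum per the labels' protocols, was labelled with Cy3 and hybridised to 1 one-colour Agilent array for WT and 1 for MeXis null. Each array held a pool of 3 samples per the series' design text. The labels name no LXR ligand or other treatment. Both arrays were on the same slide and were scanned on the same day, so neither separates the groups.

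The deposited scanner files hold the intensity of each spot on a linear scale, made with Agilent Feature Extraction 11.5.1.1 per the file headers. Per the file headers the software subtracted background and removed fitted trends across the array surface, and it gives an error for each processed signal. Probe coordinates are on mm9 per the file headers. The deposited series matrix intensity equalled the processed signal in all 62976 features of both arrays (medians 12.9 and 17.0 over all features), so its scale is linear and it is not centred. The matrix had 0 columns without a sample.

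The main values were log2 of the processed signal minus each array's 75th percentile. Because under 50% of probes were well above background, the percentile was taken over probes well above background on both arrays. Control spots were left out, as were spots that the software marked as outliers on either array (305 on WT and 205 on MeXis null); no spot was saturated. The list members Abcg1, Cd36, Jun and Lipa were thereby left out of the main values. Spots of one probe were averaged on the log2 scale, which left 56351 probes and lost 254. Probe names were updated through a RefSeq gene table of GRCm38.p6, used for names only: 33889 probes matched by accession, 9462 by symbol and 489 by synonym, and 12765 kept the name in the file. A gene was represented by its probe with the highest mean log2 signal. Of 36907 gene names, 15465 were above background on both arrays, 452 on MeXis null only and 1608 on WT only. The lowest signal well above background was lower on WT (12.1) than on MeXis null (27.3), which favours calls on WT only. A gene above background on 1 array was given a bound, the bright value against the higher of the dim probe's own signal and the lowest signal well above background on the dim array.

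With 1 array per genotype the difference has no replicate check. Genes were counted by fold thresholds of 2, and members of gene lists were called higher or lower at 1.5-fold where the difference also exceeded 1.96 times the scanner error. A list median was set against 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. The spread between spots was taken from probes with at least 5 usable spots. The 30 gene lists, the main settings and the alternatives below, apart from those named as added, were fixed before the data were examined. So was the rule for named genes: MeXis, Abca1 and every measured LXR target; the 10 genes furthest from 0 in each direction with an official symbol, a signal above background on both arrays, a difference beyond 1.96 times the scanner error and no disagreeing probe; the 5 largest bounds in each direction; the 2 highest and 2 lowest members of each list; every sex-linked gene; and every measured gene near Abca1. The values of 2 genes that this rule names are not reported here. Abcg1, Epx, Prg2, Ccr3, Gpr17, Fshb and the marker genes named only in the closing section were named after their values were seen.

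The alternatives were normexp background correction with an offset of 50, quantile normalization, loess on level with a span of 0.3, scaling to the median, the series matrix values, no filter or a stricter filter on dim probes, the median of a gene's probes, outlier spots kept, thresholds of 1.5-fold and 3-fold, genes beyond the scanner error, and LXR members above background on both arrays. Added after seeing the data were the 75th percentile of all non-control probes, scaling to the spike-in probes, and a local surface correction that subtracted from each spot the median difference of its 100 nearest spots above background on both arrays. That correction lowered the SD between spots of one probe from 0.47 to 0.33. After seeing the data, 3 further marker lists (fibroblast, mesothelial and B cell) were added. Cd72 was left out of the further B cell list after its value had been seen, and the list was therefore also run with it.

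The steps were tested on simulated data: the WT array against a copy with normal noise of the size seen between replicate spots and 200 changed genes. Of genes changed 4-fold 99.0% were counted at 2-fold and of genes changed 2-fold 57.0%, with 481 of the unchanged genes among the 15435 genes counted too. With a simulated trend across the surface 51.0% of genes changed 2-fold and 648 unchanged genes were counted, and a list shifted in the simulation had a median of -0.51 against -0.73 without the trend and with the trend corrected. Normal noise understates the real spots, whose deviations reached 2-fold more often. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays limits the precision of every value.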

Results

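Gene expression was measured in peritoneal macrophages, the macrophages of the abdominal cavity, from wild-type (WT) mice (strain given as bl6) and from mice without MeXis, a long noncoding RNA gene that lies near Abca1 on chromosome 4. The comparison addresses how loss of MeXis relates to the genes of macrophage cholesterol efflux, the export of cholesterol from the cell. Each genotype was represented by 1 one-colour Agilent array of 62976 features, hybridised with RNA pooled from 3 samples. There was therefore no replicate array, no test of the genotype and no p-value, and every difference below is between these 2 arrays. All differences are log2 values of MeXis null minus WT. On the WT array 28463 of 59305 non-control spots were well above background, and on the MeXis null array 26257 (44.3%). The only measure of error beyond the scanner's own came from 285 probes printed about 10 times on each array. The difference between arrays varied among spots of the same probe with a median SD of 0.47, more than double the median scanner error of 0.20. For a gene read from 1 spot, a difference of 0.91, or 1.88-fold, was taken as the limit of this spread. Within an array, 11.2% of pairs of spots of one probe on WT and 5.04% on MeXis null lay at least 2-fold apart. The 1.5-fold used below for members of gene lists lies inside the limit of 0.91. Of all 15465 genes above background on both arrays, 2881 were at least 1.5-fold higher and 2228 at least 1.5-fold lower, scanner error aside.

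The deleted transcript could not be used to check the labels. The 1 MeXis probe (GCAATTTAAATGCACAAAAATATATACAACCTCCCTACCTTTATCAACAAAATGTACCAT, chromosome 4, 53274285 to 53274344, mm9) gave a processed signal of 12.3 on WT and 8.44 on MeXis null, and was not well above background on either array. No fold is given, and whether the probe lies in the deleted part is not stated in the labels.

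Abca1, the transporter that passes cellular cholesterol to apolipoprotein A-I, was 3.13-fold lower in MeXis null, a difference of -1.64. Its brighter probe (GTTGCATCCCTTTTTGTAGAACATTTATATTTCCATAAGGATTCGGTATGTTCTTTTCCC, chromosome 4, 53043944 to 53044003, mm9) read 4339 on WT and 1478 on MeXis null. A dimmer Abca1 probe was well above background on WT only, with a bound of 3.08-fold lower in MeXis null. Its difference of -2.80, with a scanner error of 1.46, did not pass the scanner error limit. The dimmer probe was therefore not counted as lower. The difference of the brighter probe exceeded the 0.91 taken as the limit of the spread between spots of one probe. Of the 10 measured genes near Abca1, 1 was at least 1.5-fold higher and 2 at least 1.5-fold lower, with a list median of -0.19 at percentile 18.3 of 10000 random lists matched on level. Apart from Abca1 the lower gene was Tmem38b, at -1.41. Slc44a1 differed by -0.36, Rad23b by -0.31 and Nipsnap3b by -0.19, while Smc2 differed by 0.34, Klf4 by 0.35 and Zfp462 by 0.66. Probes of the same gene disagreed in sign for Slc44a1, Rad23b and Smc2. After a correction for uneven signal across the array surface, chosen after the data were seen and called local surface correction here, Abca1 was at -1.47, Tmem38b at -0.75 and Zfp462 at 0.26. Fsd1l was well above background on WT only, with the higher scaled value on MeXis null, so no fold is given.

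Target genes of the liver X receptors (LXR), the sterol-sensing nuclear receptors that control cholesterol efflux and lipogenesis, were lower in MeXis null as a list. Of 22 measured members, 13 were at least 1.5-fold lower and 1 at least 1.5-fold higher, and at 2-fold the counts were 8 and 0. The median difference was -0.77, below the medians of all 10000 random lists, whose SD was 0.14. The stearoyl-CoA desaturase Scd1 was 9.19-fold lower and Scd2 differed by -2.07. The apoptotic cell receptor Mertk was 3.90-fold lower, fatty acid synthase Fasn 2.90-fold, transglutaminase Tgm2 2.84-fold, Mylip (which directs degradation of the LDL receptor) 2.70-fold and the phospholipid-remodelling enzyme Lpcat3 2.67-fold. Smaller differences were seen for Lpl (-0.98), Apoc2 (-0.88), Nr1h3 (-0.83), Pltp (-0.71) and Cd5l (-0.67), of which only that of Lpl exceeded 0.91. Acaca (-0.57), Smpdl3a (-0.36), Srebf1 (-0.07), Elovl5 (0.12), Apoe (0.16), Arl4c (0.21) and Abcg8 (0.46) were within 1.5-fold. Rnf145 was 1.79-fold higher. Apoc1 was above background on WT only, with a difference of -0.64 that did not pass the scanner error limit, and was not counted as lower. The single probe of Abcg1 carried an outlier mark of the scanner software and was left out; with marked spots kept it read 23160 on WT and 7304 on MeXis null. With the local surface correction the list median was -0.84. Mertk was then at -0.98 and Srebf1 at -0.69, Nr1h3 (-0.52), Pltp (-0.53) and Cd5l (-0.54) were within 1.5-fold, and Apoe (-0.03) and Elovl5 (-0.17) lay below 0. Apoc1 (-1.17) and Acaca (-0.65) were then more than 1.5-fold below WT.

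**Figure D1:**
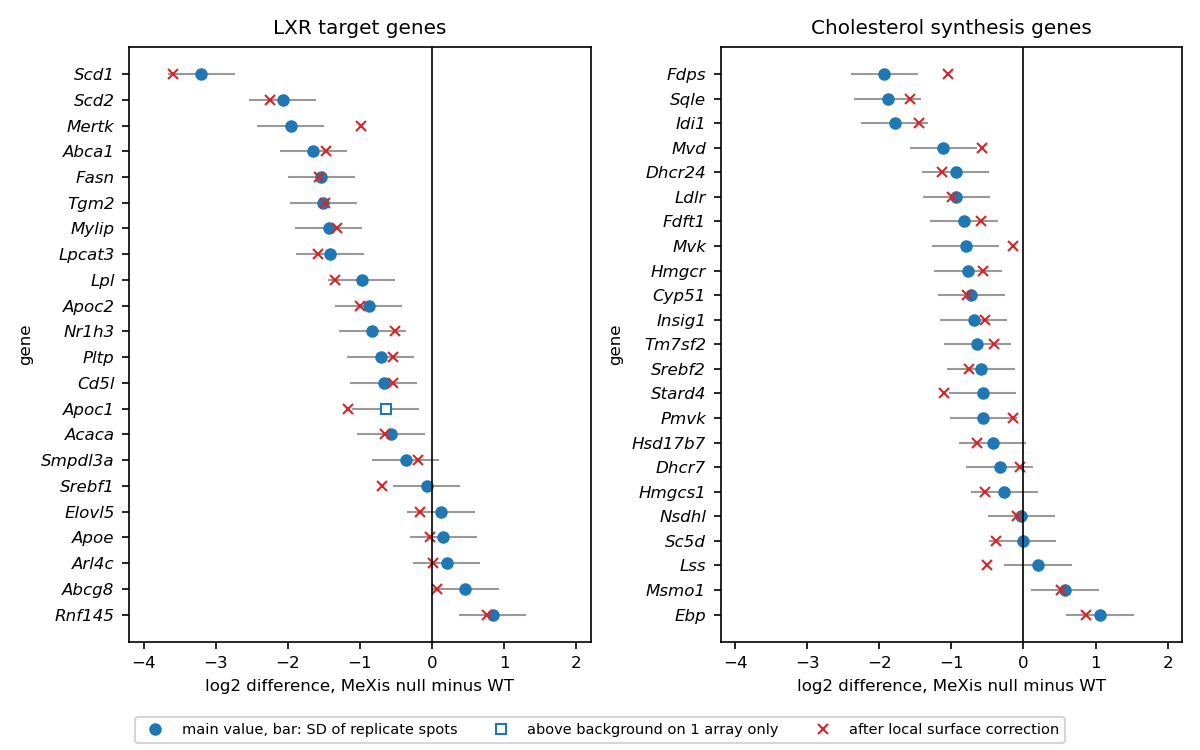
Log2 differences, MeXis null minus WT, of the measured LXR target genes (left) and cholesterol synthesis genes (right), 1 array per genotype. Filled circles are genes above background on both arrays, open squares genes above background on 1 array, bars the SD of 0.47 between spots of one probe, and crosses the values after local surface correction; most points lie left of 0, with Scd1 at -3.20 and Abca1 at -1.64.

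Genes of cholesterol synthesis were also lower in MeXis null. Of 23 measured members, 13 were at least 1.5-fold lower and 1 at least 1.5-fold higher, with 4 and 1 at 2-fold. The median was -0.64, again below all 10000 random lists. Farnesyl diphosphate synthase Fdps (3.81-fold) and squalene epoxidase Sqle (3.69-fold) were the lowest, while the sterol isomerase Ebp was 2.09-fold higher and Msmo1 differed by 0.58. After local surface correction the list median was -0.56, with 10 genes lower, and Fdps was at -1.04. Among 14 measured genes of fatty acid synthesis, 5 were lower and 1 higher by 1.5-fold, and the median of -0.25 lay at percentile 7.73, or was -0.43 over genes above background on both arrays. Malic enzyme Me1 was 3.78-fold higher, opposite to Scd1, Scd2 and Fasn, and Fads2 differed by 0.61. In the list of LXR, RXR and coregulators, 2 of 17 were higher and 5 lower, with a median of -0.25 at percentile 7.17, or -0.35 at percentile 0.66 after local surface correction. The coregulator helicases Ddx17 and Ddx5 differed by -0.83 and 1.00, and Ep300 by 1.33 (0.74 after local surface correction). Probes of the same gene disagreed in sign for Ddx17, Ddx5, Ep300, Ebp and Msmo1. Ddx17 was at 0.03 and Ep300 at -0.17 with another background correction (normexp), and Ep300 was at -0.30 and Fads2 at -0.65 by the median of their probes.

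Genes of lipid uptake and storage were not lower as a list: 5 of 15 were at least 1.5-fold higher and 3 lower, with a median of 0.32 at percentile 96.9. After local surface correction 6 were higher and 1 lower, and the median was 0.44. The fatty acid binding protein Fabp5 was 5.36-fold higher, a difference of 2.42 that was 1.65 after local surface correction. The VLDL receptor Vldlr was at least 3.22-fold higher, above background on MeXis null only. The HDL receptor Scarb1 was 2.43-fold lower, and Nceh1 differed by -0.72 (-0.42 after local surface correction). The 2 Scarb1 probes disagreed in sign. Among 15 matrix and foam cell genes 5 were higher and 1 lower (median 0.14, percentile 70.7). After local surface correction their median was 0.30 (percentile 94.9) and Mmp14 was at 0.99. Mmp14 was 3.16-fold and Gpnmb 2.74-fold higher, cathepsin K (Ctsk) was 2.57-fold lower, and Mmp9, above background on WT only, differed by less than its scanner error.

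General macrophage genes had a median of 0.12 (percentile 78.9), or 0.08 after local surface correction, with 7 of 21 higher and 3 lower by 1.5-fold. Cebpb (3.15-fold) and Lgmn (2.95-fold, a difference of 1.56 that was 0.89 after local surface correction) were higher, and Csf1r (-0.88), whose 2 probes disagreed in sign, was lower. Monocyte and MHC class II genes were lower, 7 of 11 against 1 higher, with a median of -0.71 at percentile 0.04. The class II transactivator Ciita was 3.43-fold and Plac8 2.86-fold lower, while H2-DMa (0.65, or 0.55 after local surface correction) and Itgax (0.45) lay above 0. Alternative activation genes had a median of -0.36 (percentile 4.09), with 6 of 12 lower and 0 higher. It was -0.22 (percentile 9.14) after local surface correction, with 4 lower and 1 higher, and -0.65 over genes above background on both arrays. Arginase 1 (Arg1) was 9.77-fold lower and Irf4 2.50-fold lower, against 0.35 for Klf4 and 0.28 for Chil3. Large peritoneal macrophage genes split, with 4 of 9 higher and 2 lower. Their median of -0.31 (percentile 7.75) became 0.14 after local surface correction, F10 was 2.23-fold higher (a difference of 1.16, or 0.59 with that correction), and Vsig4 (0.94), Naip1 (-0.71) and Cd5l (-0.67) differed less.

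Inflammatory cytokines and NF-kB targets went both ways, 3 of 12 higher and 2 lower (median 0.20, percentile 83.0). After local surface correction 4 were higher and 2 lower, and the median was 0.41 (percentile 98.9). Cxcl1 was 3.80-fold and Ccl2 2.39-fold higher, and Tnfaip3 was 3.33-fold and Il1a 2.23-fold lower. Among 20 interferon-stimulated genes 5 were higher and 3 lower, with a median of 0.00 (percentile 44.4). Cxcl10 (4.22-fold) and Oas2 (3.00-fold) were higher, and Usp18 (-0.78) and Ddx58 (-0.70) lay below 0. Immediate early genes (median 0.14, percentile 71.6, and 0.02 after local surface correction), unfolded protein and amino acid stress genes (-0.17, percentile 15.8), hypoxia and glycolysis genes (-0.08, percentile 29.6) and NRF2 targets (-0.01, percentile 42.8) had medians nearer 0. The sign of the hypoxia and glycolysis, NRF2 and interferon-stimulated medians depended on the scaling or the local surface correction. The 2 highest and 2 lowest members of each of these 4 lists were Ier2 (1.60), Zfp36 (-0.95), Fosb (0.73), Egr2 (-0.65), Asns (0.65), Trib3 (0.22), Chac1 (-0.64), Sesn2 (-0.61), Vegfa (-2.39), Ndrg1 (-0.73), Egln3 (0.74), P4ha1 (0.36), Nqo1 (1.00), Srxn1 (0.89), Gclc (-0.70) and Hmox1 (-0.66). After local surface correction Ddx58, Zfp36, Egr2, Asns, Sesn2, Ndrg1, Gclc and Hmox1 were within 1.5-fold, with Gclc at 0.04 and Trib3 at -0.09, while Vegfa was at -1.58 and Cxcl10 at 1.49. Probes of Vegfa, P4ha1, Asns and Ddx58 disagreed in sign. Common reference genes had a median of 0.09 (percentile 60.6), which was 0.00 with loess scaling, from Pgk1 at -0.52 and Sdha at -0.48 to B2m at 0.38 and Eef1a1 at 0.87.

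Markers of other cell types differed between the pools, beside all of the groups above. Fibroblast genes had a median of 1.03, above all 10000 random lists, with 8 of 12 at least 1.5-fold higher and 1 lower. Fbn1 was 3.57-fold and Loxl1 2.70-fold higher, but Col3a1 differed by -0.15 (0.12 after local surface correction) and Lum, above background on WT only, was at least 3.45-fold lower. Mesothelial genes had a median of 0.97 (percentile 99.9), with 5 of 8 higher and 0 lower, among them Wt1 (3.03-fold) and Upk3b (2.70-fold), with Msln at 0.46 and Krt8 at 0.27. Upk3b was at 0.67 after local surface correction, against 1.43. B cell genes had a median of -0.87 (percentile 0.01), or -0.71 with genes above background on 1 array at their bound, and 6 of 10 were lower and 0 higher. Cd79b was 3.28-fold lower and Pax5 at least 1.99-fold lower, against -0.24 for Fcrla (-0.94 after local surface correction) and -0.15 for Cd22 (0.13 with that correction), whose probes disagreed in sign. Eosinophil genes had a median of -2.28, below all random lists, over 4 members of which 3 were lower. Only Siglecf was above background on both arrays, and Ear1, Ear2 and Il5ra were on WT only. The ribonucleases Ear2 and Ear1 were at least 45.8-fold and 14.0-fold lower, Siglecf differed by -0.75, and no fold is given for Il5ra. The eosinophil granule genes Epx and Prg2 and the receptor gene Ccr3 were not well above background on either array. The median is that of Ear1, Ear2, Siglecf and Il5ra, and lies midway between Ear1 (-3.81) and Siglecf (-0.75). Of 15 spots near that of Ear2 that were dim on MeXis null, 5 were also bright on WT. The Ear genes are near-identical copies, so their probes may not tell them apart.

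The remaining cell type lists had few measured members. T and NK cell genes had a median of -0.28 (percentile 10.9; 3 of 8 lower), with Cd5 at least 2.70-fold and Cd2 2.43-fold lower, Cd4 at 0.09 and Prf1 at 0.59. The 4 measured mast cell genes had a median of -1.48 (percentile 1.41), or -0.43 with bounds, with Cma1 at least 2.37-fold lower, Hdc at -0.32 and Tpsb2 at 0.28. Cpa3, above background on WT only, did not pass the scanner error limit. Neutrophil genes had a median of -0.55 (percentile 4.45), or -0.25 with bounds. Csf3r differed by -0.77, Mmp8 by 0.13 and Elane by 0.19, and Cxcr2, above background on WT only, did not pass that limit. Endothelial genes had a median of 0.31 (percentile 77.6), or 0.68 (percentile 96.8) after local surface correction, with Pecam1 at least 2.28-fold lower, Egfl7 at least 2.28-fold higher, Esam 2.13-fold higher and Vwf, whose probes disagreed in sign, at 0.11. None of the 6 erythroid genes was well above background on either array. Of the sex-linked genes Xist differed by -0.20 and Kdm5d was above background on WT only with no fold, and Ddx3y, Eif2s3y and Uty were not well above background on either array.

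Cell cycle genes were higher in MeXis null, 12 of 19 against 2 lower by 1.5-fold, with a median of 0.87 at percentile 99.99. Top2a was 3.54-fold higher and Bub1 at least 3.75-fold higher, while Cdk1 (-0.75) and Mcm3 (-0.60) were lower, and within 1.5-fold after local surface correction. Probes of Mcm3 disagreed in sign.

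**Figure D2:**
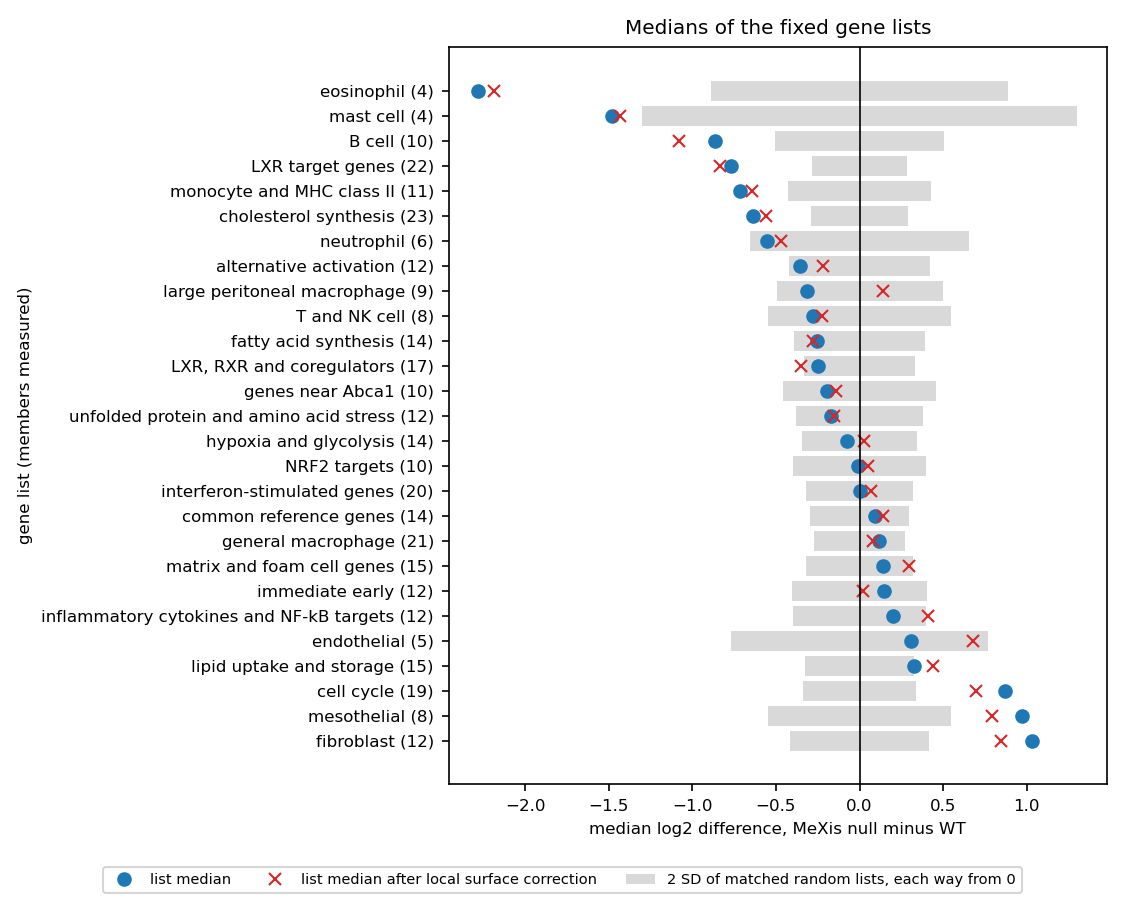
Median log2 difference, MeXis null minus WT, of each fixed gene list with at least 3 measured members (number in brackets), 1 array per genotype. Circles are list medians, crosses the medians after local surface correction, and grey bars 2 SD of matched random lists on each side of 0; fibroblast (1.03), mesothelial (0.97) and cell cycle genes (0.87) lie to the right and eosinophil genes (-2.28) furthest to the left.

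Across all 15465 genes above background on both arrays, 1132 were at least 2-fold higher and 739 at least 2-fold lower in MeXis null. Among genes with an official symbol and no probe of opposite sign, the highest was the peroxidase Gpx8 (8.12-fold), followed by Rn7sk (6.39-fold), E2f5 (6.08-fold), Adamts9 (5.90-fold), Syt13 (5.79-fold), Nucb2 (5.73-fold), Plaa (5.44-fold), Fabp5 (5.36-fold), Olfr521 (5.27-fold) and Lrrc20 (5.15-fold). After Arg1 and Scd1, the lowest were the organic anion transporter Slco2b1 (7.35-fold), the VIP receptor Vipr1 (7.18-fold), Zmat3 (a difference of -2.81), Clec16a (6.56-fold), the lipoprotein lipase inhibitor Angptl4 (6.09-fold), Smap1 (6.03-fold), Vsig8 (a difference of -2.59) and Adgrb3 (5.69-fold). The log2 differences of several of these genes were smaller by more than 0.5 after local surface correction, to 1.89 for E2f5, 2.0 for Adamts9, 2.0 for Syt13, 2.0 for Nucb2, 1.65 for Fabp5, 1.59 for Olfr521, -2.21 for Vipr1, -1.99 for Zmat3, -1.85 for Clec16a, -1.78 for Smap1 and -1.69 for Adgrb3. Some of the folds rest on a dim signal on 1 array. On WT Gpx8 read 38.5, E2f5 34.5, Syt13 34.4, Adamts9 50.2 and Olfr521 22.6. On MeXis null Vipr1 read 38.8, Arg1 44.6 and Clec16a 51.6. The lowest signals well above background were 12.1 on WT and 27.3 on MeXis null. Others, such as Fabp5 and Angptl4, were bright on both arrays. The deviations of replicate spots from their own mean reached 2-fold in 8.0% of cases, which over 15465 genes would give 1237 genes from spot noise alone, against the 1871 counted. After the local surface correction the counts were 720 higher and 402 lower, against 444 expected from spot noise, and 582 of the higher and 306 of the lower genes were counted under both settings. Of 562 genes at 2-fold with several probes above background, 294 had all such probes on the same side of 0. For a gene with 2 probes, unrelated signs would agree about as often as not. The count was not split by number of probes, and it is no clear support for the 2-fold calls.

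A further 394 genes were above background on MeXis null only and at least 2-fold higher, and 197 on WT only and at least 2-fold lower. These were 394 of 452 and 197 of 1608 genes above background on 1 array only. The lowest signal well above background was 12.1 on WT and 27.3 on MeXis null. A gene at the MeXis null limit thus already lies above the WT limit, so the 2 counts do not compare the directions on equal terms. The largest bounds on MeXis null were those of the secreted Wnt modulator Sfrp2 (at least 21.3-fold), Gjb5 (9.89-fold), Prss35 (9.33-fold), Trpv6 (8.0-fold) and Zfp786 (7.25-fold). On WT they were those of Stxbp4 (at least 242-fold), Clnkos (163-fold), Mov10l1 (98.0-fold), Ear2 (45.8-fold) and the immunoglobulin gene Ighg3 (23.2-fold). The spots of Stxbp4 (row 359, column 51) and Clnkos (row 361, column 50) lay close together on the array. The spot of Mov10l1 (row 253, column 121) lay on 1 diagonal with those of Gpr17 (row 244, column 130) and Fshb (row 243, column 131), which were also bright on WT only.

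**Figure D3:**
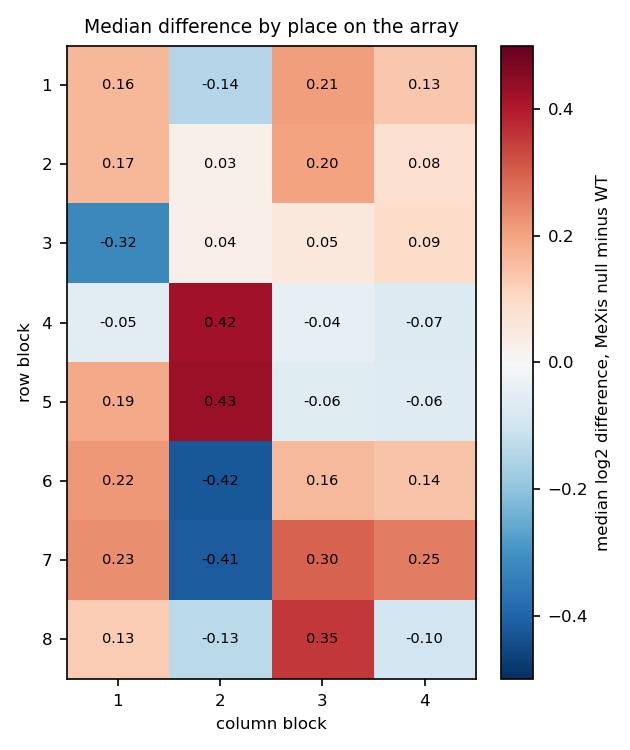
Median log2 difference, MeXis null minus WT, of spots above background on both arrays in 32 blocks of 48 rows by 41 columns, by place on the array. Colour and printed value give the median of each block, which ran from -0.42 to 0.43, so that the difference between the arrays varied with place.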

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

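The local surface correction, the 75th percentile of all probes and the spike-in scaling were chosen after seeing the data. Abca1 stayed lower under each alternative run, from -1.46 with normexp to -2.22 with the median of its probes. That median includes the dim probe, which did not pass the scanner error limit. The LXR median stayed below 0 throughout and moved by more than the SD of random lists only with normexp, to -0.61. The counts of genes at least 2-fold higher and lower were 6298 and 1825 with no dim probe filter and 493 and 446 with the stricter one, which count more and fewer genes by construction. They were 2881 and 2228 at 1.5-fold, 226 and 171 at 3-fold, and 720 and 402 after the local surface correction. Under median scaling the share of higher genes was 50.9%, against 60.5% in the main setting. It was 51.25% with normexp, 52.5% with the stricter dim probe filter and 53.5% with the 75th percentile of all probes. Loess gave 53.7%, quantile normalization 54.2% and spike-in scaling 54.8%. The share was higher with the median of probes (63.5%), the local surface correction (64.2%) and no dim probe filter (77.5%). Genes measured on 1 array only were 13 higher and 45 lower with normexp, whose offset raises dim signals, against 394 and 197 in the main setting; the dim probe filters do not apply to these genes and were not run for them. Signs turned for Ddx17 (0.031) and Ep300 (-0.17) with normexp, for Ep300 (-0.30) and Fads2 (-0.65) with the median of probes, for Gclc (0.036) after local correction, and for the mast cell median (0.29) with no dim probe filter; the cause was not tested. Medians within 2 SD of random lists turned sign too. These were the large peritoneal macrophage median after local correction (0.14) and with no dim probe filter (0.65), those of the genes near Abca1 (0.08), the T and NK cell genes (0.09) and the alternative activation genes (0.01) with no dim probe filter, and that of the immediate early genes with the stricter one (-0.28). Those of the interferon-stimulated, NRF2, hypoxia and reference genes turned sign under at least 1 alternative each, by less than the SD of random lists. With normexp the fibroblast median was 0.56, the mesothelial 0.55, the cell cycle 0.54 and the B cell -0.48, all with their sign kept, and with the stricter filter the cell cycle median was 0.38. Of the other values that an alternative altered at all, 1160 for genes and 290 for list medians moved by less than their spread, and 100 and 41 by more without a called sign turning. The series matrix values repeat the main ones and show nothing about stability. MeXis was below background on both arrays, so no fold was computed for it under any alternative. No array could be left out, since each group has 1 array. No paired analysis was possible because each group has 1 array. Fewer than 50% of the probes stood well above background, so folds of dim genes are bounds.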

Other observations

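The tests of the macrophage share and of the genes shared with synthesis were chosen after the values they rest on had been seen. So were those of the brightest fibroblast genes and of neighbouring spots. The other tests were set before their results were seen, on patterns already found in these data. The further B cell test is in part an exception, since Cd72 was left out of its list after its value had been seen.

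Marker genes not in the first lists differed in the same direction as those lists. The further fibroblast list had a median of 0.91 over 14 measured genes, with 8 at least 1.5-fold higher, among them Serpinf1 (1.76), Timp3 (1.68) and Bgn (1.65), while Fstl1, whose probes disagreed in sign, differed by -0.42. All 6 measured genes of the further mesothelial list were higher (median 1.47), including Nkain4 (1.92) and Rspo1 (1.66). All 11 measured genes of the further B cell list were lower (median -1.14), with a bound of -2.74 for Vpreb3, above background on WT only. Of these, Blnk is also expressed by macrophages, read 62383 on WT, and was at 0.10 after local surface correction. Cd55 was then at -0.13, and 3 of its 4 probes were higher in MeXis null. With the correction 8 of the 11 genes were at least 1.5-fold lower. Cd72 had been left out of that list after its value of 2.05 was seen, and with it the median was -1.12.

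LXR target genes were lower in MeXis null. The list median of -0.84 after local correction argues against uneven signal across the array as the whole cause. The general macrophage median of 0.12, on the same scaling, argues against a lower share of macrophages as the whole cause. Each array was scaled to its own probes above background, so the macrophage median does not measure the share itself. LXR targets outside both synthesis lists had a median of -0.77, which argues against genes shared with sterol and fatty acid synthesis as the whole cause. Loss of MeXis remains a hypothesis that 1 pool per genotype cannot test, as do differences between the pools in cell types other than macrophages.

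Fibroblast, mesothelial and cell cycle genes were higher in MeXis null. Together they kept a median of 0.70 after local correction, against uneven signal as the whole cause. A lower share of macrophages alone, with the other cell types unchanged relative to one another, would raise them alike, but the B cell median was -0.87. A lower share of macrophages together with fewer B cells was not excluded. More fibroblasts and mesothelial cells in the MeXis null pool are a candidate explanation, since the further markers of both had a median of 1.11. For fibroblasts alone, more cells and a change within them cannot be told apart: the 5 list members brightest on WT (Acta2, Col1a2, Dcn, Col1a1 and Col3a1) had a median of 0.37, but choosing by WT signal favours low differences, and the 5 brightest on MeXis null or by mean level, with Col6a1 for Col3a1, had a median of 0.74; no cell type test covered the cell cycle genes.

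Among the 197 genes bright on WT only, local marks on the WT array may account for a part. Around their spots 16.6% of neighbours dim on MeXis null were above background on WT, against 8.95% around all such dim spots, a ratio of 1.86. The same count for the 394 genes bright on MeXis null only gave 14.3% against 2.41%, a ratio of 5.94, so clustering was not particular to the WT array. The 2 ratios do not compare the arrays on equal terms. Their base shares differ, as do the lowest signals well above background (12.1 on WT and 27.3 on MeXis null). Fewer B cells in the MeXis null pool are a candidate source of another part, given the further B cell median of -1.14 (-1.12 with Cd72). In that list, however, 7 of the 11 measured genes were above background on both arrays and so are not among the 197. B cell genes among the 197 were not counted, so the median is no direct evidence on them. Of the named genes, 4 of 14 such neighbours of Stxbp4, 6 of 17 of Clnkos, 4 of 14 of Mov10l1 and 5 of 15 of Ear2 were bright, and 0 of 14 of Ighg3, while for the genes bright on MeXis null only these were 0 of 11 for Sfrp2, 0 of 17 for Gjb5, 0 of 11 for Prss35, 0 of 11 for Trpv6 and 2 of 15 for Zfp786.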
